A study of Homo sapiens with 4 samples.

How the data were processed

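MicroRNA (miRNA) levels were measured in 4 total RNA samples of HaCaT cells, an immortalized human keratinocyte line. Cells received negative control RNA oligonucleotides (siCtrl) or an siRNA against YAP (siYAP) and were then kept at high density, per the labels' protocols. Each condition had 2 samples. RNA was extracted with TRIzol and read with the nanoString nCounter miRNA assay, which counts a colour-coded barcode for each probe that finds its target, with no amplification step recorded in the labels. The software and its settings are not given in the sources used here.

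The deposited table held 822 rows, of which 800 were human miRNA probes, 5 were housekeeping mRNA probes, 6 were positive controls, 6 were negative controls and 5 were probes for plant or worm miRNAs. The deposited values are a scaled signal. In the human miRNA and housekeeping rows the authors had multiplied whole barcode counts by 1 factor per sample, which was worked out from the values themselves. The factors were 1.04 for siCtrl 1, 1.02 for siCtrl 2, 1.20 for siYAP 1 and 0.826 for siYAP 2, and dividing by them gave whole counts for 100% of these 805 rows within a tolerance of 0.05. The control rows were deposited as unscaled counts. The factors ran against the positive controls, synthetic targets added at fixed amounts: they deviated by at most 1.01% from factors set on the geometric mean of the 3 strongest, and by up to 73.4% from factors set on the total human miRNA count. The exact formula was not settled. The median human miRNA count of a sample (17 to 24) lay near the mean of its negative controls (17.2 to 25.2), so background had not been taken off the panel as a whole, and a step applied to single probes is not excluded. A scale of this kind corrects for how well a lane was read but not for how much RNA entered it, so a difference in RNA input between samples would appear as a shift shared by all miRNAs.

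The 4 samples held 55079 (siCtrl 1), 76435 (siCtrl 2), 125119 (siYAP 1) and 177355 (siYAP 2) human miRNA counts, and 36928, 36428, 32806 and 46510 positive control counts in the same order. Background was set in each sample at the mean plus 2 SD of its negative controls, at 51.4, 39.0, 35.4 and 53.4 counts, which is 53.5, 39.7, 42.3 and 44.1 on the deposited scale. A probe was tested if it lay above background in both samples of at least 1 group, which left 182 probes. The samples of each group were compared before averaging. A chi-square test of their counts gave 5.24 per degree of freedom for the siCtrl pair and 5.30 for the siYAP pair, beyond sampling noise, and each sample was counted as 1 replicate. The labels do not say whether the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

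Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(deposited signal + 1), so folds are on that scale and understate changes of dim probes. The Benjamini-Hochberg threshold was 0.05 over the 182 tested probes. The deposited scale was kept, since rescaling on the miRNAs themselves removes a shift that most of them share. Where a probe was below background in both samples of a group, a fold is given as a lower bound, with each dim reading raised to that sample's background. The 22 miRNA lists (families, genomic clusters, epidermal miRNAs, miRNAs linked to steps of miRNA processing, and miRNAs of other cell types) were fixed before the data were examined. Lists with at least 3 tested probes were compared with the other tested probes by limma's camera with a preset correlation of 0.01 and by camera with an estimated correlation, and were tested against no change by fry. Sample medians were compared by a two-sided exact permutation test. Named miRNAs follow a rule fixed in advance: the 10 largest rises and the 10 largest falls past the threshold by limma log2 difference, the 5 probes with the highest mean, up to 4 of the brightest tested members of each list, and the control probes. Of the probes, 10 name several miRNAs. Members of a family with near-identical sequences can share signal on such probes, so their separate values are uncertain.

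The alternatives covered 5 other scalings, 2 other pseudocounts (10 and 50), other filters on dim probes, a background of 3 SD, limma without the trend, each sample left out in turn and the replicate number as a block. Another 6 were added after seeing the data, among them edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered counts. On simulated counts for the 800 probes, with 200 changed by known folds in each of 20 simulations, the limma step called 75.2% of the tested 2-fold changes and 100% of the 4-fold changes, and 4.2% of its calls were false. With no change simulated it called a median of 0 and at most 1 probe. These rates hold for the simulated setting, whereas 131 of the 182 tested probes were called in the data. Neighbouring miRNA genes were found through a gene table of the GRCh38.p14 assembly, used only for which genes lie near each other, in which 173 of 176 single-miRNA probes were matched. Values were read and plotted with Python 3.11, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.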

Results

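MiRNA levels were compared between HaCaT keratinocytes treated with negative control oligonucleotides (siCtrl, n = 2) and with siRNA against YAP (siYAP, n = 2), a transcriptional co-activator held in check by the Hippo pathway. The question was how lowering YAP changes miRNA levels across the panel in densely grown cells. The panel has no probe for the YAP mRNA, so the extent of the knockdown was not measured here. Each sample gave between 55079 and 177355 human miRNA counts. Of the 800 human miRNA probes, 133 lay above background in siCtrl 1, 196 in siCtrl 2, 193 in siYAP 1 and 179 in siYAP 2. The 10 brightest probes held 29.9% and 35.7% of the siCtrl counts and 43.2% and 43.3% of the siYAP counts.

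Most miRNAs above background were higher after YAP siRNA. Of the 182 tested probes, 120 rose, 11 fell and 51 did not pass the test (limma, Benjamini-Hochberg adjusted p under 0.05). The median tested probe was 2.21-fold higher in siYAP (log2 difference 1.15), and 102 of the 120 rises were over 2-fold and 24 over 4-fold. The summed human miRNA signal was 57347 and 77729 in the siCtrl samples and 149645 and 146502 in the siYAP samples, a ratio of 2.19. The median signal of the tested probes was 72.4 and 79.8 in siCtrl against 154.9 and 144.6 in siYAP. Both siYAP medians lay above both siCtrl medians, and the exact two-sided permutation p was 0.333, the smallest that 2 against 2 samples allow. Both siYAP samples lay above both siCtrl samples for 142 tested probes and below them for 22, where chance gives a non-overlap in 33.3% of probes. The probes share the same 4 samples, so a shift of a whole sample moves many at once and these counts are not a test. Of the 120 rises, 21 were below background in both siCtrl samples and were tested through siYAP alone.

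The control probes did not all move alike. The negative controls differed by between -0.10 and 0.09 on the log2 scale. Of the housekeeping mRNAs, GAPDH was 1443.6 ± 124.5 in siCtrl and 3343 ± 882 in siYAP (SD, n = 2), 2.28-fold higher, and RPL19 was 1399 ± 69 and 2445 ± 355. RPLP0 was 2877 ± 266 and 3917 ± 196, B2M was 537 ± 30 and 630 ± 63, and ACTB was 409 ± 20 and 329 ± 51. The probe for the rice miRNA osa-miR442 was 39.1 ± 5.2 in siCtrl and 115.4 ± 16 in siYAP. The 551 probes that were above background in no sample had a median log2 difference of -0.32. On the deposited scale 120 probes rose and 11 fell. The split was 66 and 21 when samples were rescaled on the housekeeping mRNAs, where the median log2 difference was 0.68. It was 42 and 46 with each sample centred on its median tested probe, 26 and 62 with scaling on the 100 brightest probes, 35 and 51 with scaling on the miRNA total, 37 and 32 with quantile normalization and 37 and 50 with edgeR's TMM, where the medians were 0.18, -0.19, 0.01, 0.10 and 0.07. Under all 6 of these scalings, 25 of the 120 rises remained called higher. Each of the 6 lowered the median of siYAP relative to siCtrl, so they do not test the 11 falls. A probe level on the deposited scale can be called lower under them.

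**Figure D1:**
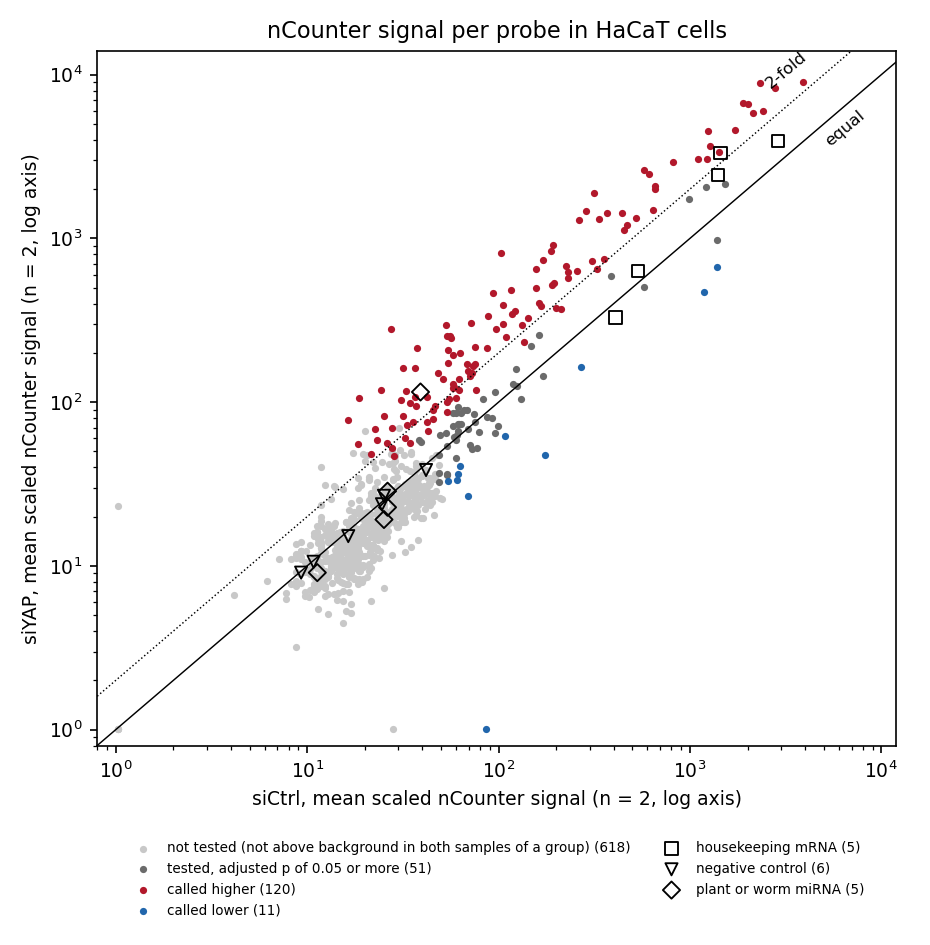
Mean deposited nCounter signal of each probe in siCtrl (x axis) and siYAP (y axis), 2 samples each, both axes logarithmic, for 800 human miRNA probes and the control probes; the solid line marks equal signal and the dotted line a 2-fold rise. Most bright miRNAs lie above the line of equality, with 120 called higher and 11 called lower on the deposited scale (66 and 21 when rescaled on the housekeeping mRNAs), while the negative controls lie on it and the housekeeping mRNAs lie on both sides.

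MiR-210, a miRNA induced by hypoxia, rose from 27.3 ± 4.1 in siCtrl, below background, to 279 ± 27 in siYAP (SD, n = 2), at least 5.93-fold (limma log2 difference 3.31, SE 0.27, adjusted p = 5.9e-14). MiR-301a-3p rose from 103 ± 46 to 818 ± 56 (8.33-fold, limma adjusted p = 2.1e-10). MiR-29b-3p, of a family that represses collagen mRNAs, rose from 314 ± 181 to 1898 ± 293 (6.55-fold, adjusted p = 1.0e-07), and miR-32-5p from 285.3 ± 207.7 to 1479 ± 152 (6.01-fold, adjusted p = 3.0e-07). MiR-34a-5p, a transcriptional target of p53, rose from 18.6 ± 3.2, below background, to 105.5 ± 11.4, at least 2.26-fold (adjusted p = 2.8e-10). MiR-30d-5p rose 5.63-fold and miR-425-5p 5.58-fold, but both were below background in siCtrl 1 (31.24 and 41.65), so these folds are uncertain. MiR-218-5p rose 5.02-fold and miR-324-5p 4.89-fold, and miR-362-5p, below background in siCtrl, rose at least 3.44-fold. For these miRNAs, from miR-30d-5p on, the limma adjusted p lay between 2.9e-10 and 3.3e-07. Of these 10, all but miR-32-5p remained called higher under each of the 6 other scalings. The siCtrl samples of a pair of them lay far apart. The log2 difference of miR-32-5p was 2.59 with all samples, 1.77 without siCtrl 1 and 3.40 without siCtrl 2, and that of miR-29b-3p was 2.71, 2.09 and 3.33.

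The brightest miRNAs of these cells rose as well on the deposited scale. The probe shared by miR-106a-5p and miR-17-5p was 3913 ± 1544 in siCtrl and 8962 ± 1707 in siYAP (SD, n = 2), 2.36-fold higher (limma adjusted p = 0.0357). MiR-15b-5p rose from 2312 ± 430 to 8893 ± 970 (adjusted p = 7.9e-04), miR-19b-3p from 2792 ± 1274 to 8287 ± 617 (0.00456), miR-25-3p from 1883 ± 150 to 6729 ± 934 (9.1e-04) and miR-19a-3p from 2022 ± 1269 to 6577 ± 1684 (0.00132). The probe shared by miR-106a-5p and miR-17-5p was lower in siYAP with scaling on the 100 brightest probes (-0.11) and with quantile normalization (-0.26). Of the 6 other scalings, miR-15b-5p was called higher under 4, miR-25-3p under 2, miR-19a-3p under 1, and miR-19b-3p and the shared probe under 0. None of these 5 probes passed the test without siYAP 1 (limma adjusted p between 0.0561 and 0.381) or without siYAP 2 (between 0.0741 and 0.241), and the shared probe also failed it without siCtrl 1 (0.0679). The log2 difference of miR-19a-3p was 1.84 with all samples, 1.15 without siCtrl 1 and 2.52 without siCtrl 2.

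MiR-155-5p, which is induced in activated immune cells, was called lower. Its counts were 94 and 72 in the siCtrl samples and 1 in each siYAP sample (limma log2 difference -5.42, SE 0.29, adjusted p = 1.4e-20). The siYAP readings lay below every negative control of their lanes, where 8 was the lowest count, and set against the background of the siYAP samples the siCtrl signal was 1.94-fold higher, so the size of any fall is not settled. MiR-3676-3p fell from 173.9 ± 1.5 to 47.4 ± 22.6 (3.83-fold, adjusted p = 2.2e-07), miR-378e from 1189 ± 80 to 473 ± 51 (2.52-fold, adjusted p = 0.00126) and miR-1283 from 1377 ± 175 to 673 ± 165 (2.07-fold, adjusted p = 0.0131). The probe shared by miR-520d-5p, miR-518a-5p and miR-527 fell from 69.0 ± 12.8 to 26.6 ± 2.1, at least 1.57-fold. MiR-570-3p and miR-144-3p fell by 0.79 and 0.71 on the log2 scale, and miR-1286, miR-4455 and miR-1273d, below background in siYAP, fell at least 1.39-, 1.4- and 1.26-fold (limma adjusted p between 0.00451 and 0.033 for these 5). Of the 11 falls, 6 had a siCtrl mean under 100 and were below background in both siYAP samples. The 551 probes above background in no sample also lay lower in siYAP, with a median log2 difference of -0.32 (0.803-fold). The small falls of dim probes were not tested against that drop. Of the 11, 4 remained called without siYAP 1, 6 without siYAP 2, 8 without siCtrl 1 and 7 without siCtrl 2. MiR-378e and miR-1283 did not pass the test without siYAP 1 (adjusted p = 0.156 and 0.384) or without siYAP 2 (0.0857 and 0.136). MiR-1286, miR-4455, miR-1273d and miR-144-3p did not without siYAP 1 (0.119, 0.128, 0.15 and 0.402), nor miR-570-3p and miR-144-3p without siYAP 2 (0.152 and 0.111). The same held for miR-1286 and miR-1273d without siCtrl 1 (0.0823 and 0.0666), and miR-4455, miR-1273d and miR-144-3p without siCtrl 2 (0.0896, 0.0701 and 0.14).

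**Figure D2:**
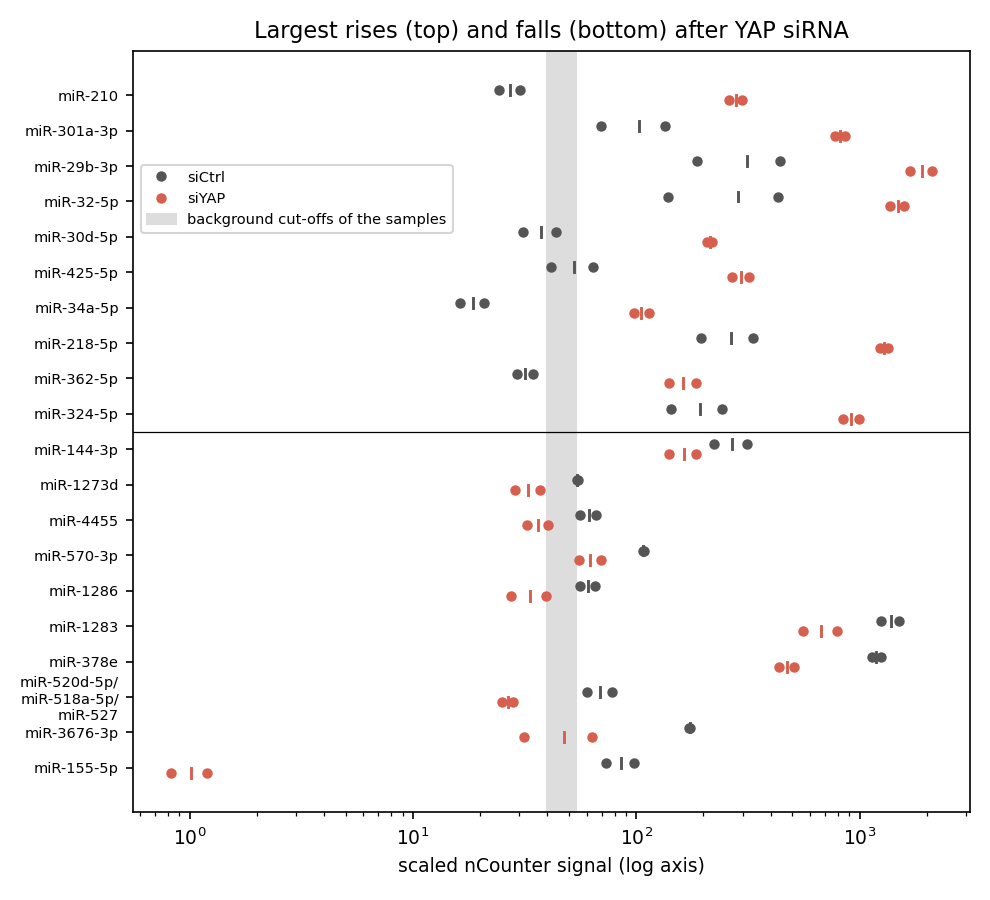
Deposited nCounter signal (log axis) of the 10 miRNAs with the largest rises and the 10 with the largest falls by limma log2 difference after YAP siRNA; points are the 2 samples of each group, short bars their means, and the grey band spans the background of the 4 samples, 39.7 to 53.5. The siYAP points of the 10 rises lie to the right of both siCtrl points on the deposited scale, and miR-155-5p in siYAP lies far below the background band.

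The fixed lists were then compared. Of the 22 lists, 20 had a tested probe and 11 had at least 3. Camera called no list different from the other tested probes at an adjusted p under 0.05 with the preset or an estimated correlation. At an unadjusted p under 0.05 limma's camera picked out the miR-30 family (0.0267) and the 14q32 cluster (0.0124), and with an estimated correlation neither (0.387 and 0.133). Fry, which asks whether a list's members move one way and not whether they differ from other probes, called 8 of the 11 lists. The numbers of members called were the same when adjusted over the list alone.

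Among proliferation-linked miRNAs, 8 of 9 tested probes of miR-17~92 and its paralogous clusters rose (median log2 difference 1.48, camera adjusted p = 0.755), with a list median above 0 under the 6 other scalings. These called 1 to 3 of the probes higher, and 3 of them called 1 lower. All 5 tested probes of the miR-15/16 family, which represses cyclin mRNAs, rose (median 1.54, above 0 under each scaling, with 0 to 3 called under the 6 others). That median is the value of miR-424-5p, which was below background in both siCtrl samples (17.7 and 19.3) and rose at least 1.21-fold. MiR-16-5p was 1275 ± 187 in siCtrl and 3691 ± 454 in siYAP, and miR-15a-5p 1241 ± 575 and 4523 ± 745 (limma adjusted p = 0.002 and 2.9e-04). MiR-503 rose from 143 ± 46 to 328 ± 46 (adjusted p = 5.0e-04), and its difference turned negative with scaling on the 100 brightest probes (-0.12) and quantile normalization (-0.03). Both probes of the cluster of miR-221 and miR-222, which represses the cell cycle inhibitor p27, rose: miR-221-3p from 817 ± 164 to 2913 ± 86 and miR-222-3p from 158 ± 21 to 652 ± 38 (adjusted p = 1.6e-04 and 4.0e-07), in the same direction under each scaling and both called under 4 of the 6 others. The let-7 family, linked to differentiation, gave a mixed picture. On the deposited scale 4 of 9 tested probes rose and none fell (median 0.57, a difference of -0.58 from the other tested probes, camera adjusted p = 0.714), but the family median was below 0 under 5 of the 6 other scalings and 0.11 with housekeeping scaling. Under the 6, 0 to 1 probes were called higher and 0 to 5 lower. Let-7a-5p was 1425 ± 261 in siCtrl and 3349 ± 236 in siYAP (adjusted p = 0.0111), let-7g-5p 521 ± 75 and 1342 ± 330 (0.00141) and let-7e-5p 190 ± 14 and 517 ± 59 (1.2e-04), whereas let-7f-5p was 148 ± 30 and 219 ± 21 (0.0729). Let-7a-5p and let-7g-5p turned negative with scaling on the 100 brightest probes, and let-7e-5p with quantile normalization. Without siYAP 1 miR-15a-5p, miR-16-5p, miR-503, miR-221-3p, let-7a-5p and let-7g-5p did not pass the test (limma adjusted p = 0.0796, 0.103, 0.0512, 0.0518, 0.188 and 0.171). Without siYAP 2 miR-16-5p and let-7a-5p did not (0.15 and 0.238).

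The miR-30 family had the smallest camera p of the lists with a median above the rest of the panel. All 5 tested members rose (median 2.0, which is 0.91 above the other tested probes, camera adjusted p = 0.147, and adjusted p = 0.851 with an estimated correlation), and the family median stayed above 0 under each scaling, with 3 to 4 members called under the 6 others. MiR-30b-5p rose from 336 ± 114 to 1313 ± 218 and miR-30e-5p from 54.5 ± 9.3 to 173.9 ± 22.7 (limma adjusted p = 7.5e-06 and 1.3e-06), while miR-30c-5p, 62.1 ± 18.6 and 138.5 ± 9.8 (2.8e-04), turned negative with scaling on the 100 brightest probes. Both miR-30e-5p and miR-30c-5p were below background in siCtrl 1 (47.89 and 48.94), so the size of these rises is uncertain. All 3 miR-29 members rose (median 1.58, above 0 under each scaling, with 1 to 2 called under the 6 others), with miR-29c-3p at 122 ± 40 and 359 ± 56. MiR-29a-3p, 58.7 ± 9.7 and 123.3 ± 28.9, turned negative under scaling on the 100 brightest probes (-0.29), the total (-0.09) and TMM (-0.04). All 4 tested probes of the miR-23/27/24 clusters rose (median 1.69, above 0 under each scaling, with 1 to 3 called under the 6 others), among them miR-27b-3p from 230 ± 85 to 620 ± 67, miR-23a-3p from 116 ± 22 to 485 ± 36 and miR-23b-3p from 54.5 ± 9.3 to 206.8 ± 25.3. In siCtrl 1 miR-23b-3p was below background (47.89), so the size of its rise is uncertain. Both tested probes of the miR-181 family rose, in the same direction under each scaling and both called under 3 of the 6 others, with miR-181a-5p at 88.4 ± 14.5 and 334.6 ± 22.3 and the probe of miR-181b-5p and miR-181d at 32.9 ± 0.9 and 117.4 ± 23.5. The shared probe was below background in both siCtrl samples and rose at least 2.49-fold. Of the clusters of miR-99, miR-100 and miR-125, 4 of 5 rose (median 1.30), and the median turned negative with scaling on the 100 brightest probes (-0.05) and quantile normalization (-0.12), with 0 to 1 probes called higher under the 6 and 1 called lower under the first of this pair. MiR-125a-5p was 439 ± 63 and 1427 ± 13, miR-99b-5p 232 ± 14 and 573 ± 31, and miR-99a-5p 133 ± 28 and 295 ± 48, the last pair turning negative under the same scalings as the median and not passing the test without siYAP 2 (limma adjusted p = 0.0525 and 0.0619).

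Among epidermal miRNAs all 5 tested probes rose (median 1.31, camera adjusted p = 0.383), with a median of -0.04 when scaled on the 100 brightest probes and 1 to 2 called higher under the 6 other scalings. With the 100 brightest probes miR-455-3p was called lower. Besides miR-210, miR-125b-5p was 453 ± 4 in siCtrl and 1130 ± 105 in siYAP, miR-24-3p 69.3 ± 17.0 and 154.9 ± 41.5, and miR-455-3p 76.1 ± 1.7 and 119.2 ± 23.1 (limma adjusted p = 0.00129, 4.5e-04 and 0.0357). MiR-125b-5p and miR-24-3p turned negative with scaling on the 100 brightest probes, and miR-125b-5p also with quantile normalization. MiR-455-3p was lower in siYAP under 5 of the other scalings, between -0.27 and -0.71, and did not pass the test in any fit without 1 sample (adjusted p between 0.0593 and 0.312). MiR-125b-5p did not pass it without siYAP 1 (0.125) or without siYAP 2 (0.0708). The other members on the panel, named after their values were seen, were not above background in both samples of a group: miR-203 read 16.4 ± 7.0 and 16.4 ± 9.6, miR-205-5p 19.6 ± 0.3 and 16.8 ± 1.6, miR-184 12.3 ± 7.1 and 8.5 ± 1.5, and miR-31-5p 27.8 ± 0.5 and 51.0 ± 12.5. Of the miR-200 family, which maintains E-cadherin in epithelia, miR-200c-3p alone was tested and rose from 26.2 ± 4.7, below background, to 56.6 ± 2.9, at least 1.22-fold (adjusted p = 4.1e-04); it turned negative with scaling on the 100 brightest probes (-0.23) and the total (-0.03). Of the p53-linked list 2 of 3 tested probes rose (median 2.17, above 0 under each scaling). Besides miR-34a-5p, miR-194-5p rose from 55.5 ± 10.7 to 251.9 ± 17.5 (adjusted p = 1.2e-08), and miR-192-5p was 118.9 ± 2.7 and 129.4 ± 0.4 (0.698) and was called lower under 5 of the 6 other scalings. The list median is the value of miR-194-5p, which was below background in siCtrl 1 (47.89), so its size is uncertain.

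Lists tied to miRNA processing had few tested probes. Of miRNAs linked to p68 and p72, DEAD-box helicases of the Microprocessor that cuts primary miRNA transcripts, 2 of 7 probes were tested. MiR-16-5p rose, and miR-21-5p was 574 ± 52 in siCtrl and 505 ± 156 in siYAP (limma log2 difference -0.22, adjusted p = 0.574), a difference that was called lower under 5 of the 6 other scalings. Of miRNAs made without the Microprocessor enzyme Drosha, 2 of 13 probes were tested. MiR-320e rose from 32.4 ± 4.2, below background, to 60.7 ± 12.3, at least 1.30-fold (adjusted p = 0.00355), turned negative under 4 of the 6 other scalings, and did not pass the test without siCtrl 2 (0.0579) or without siYAP 1 (0.0744). MiR-484 was 61.2 ± 1.2 and 93.3 ± 37.3 (adjusted p = 0.0734) and was called lower with scaling on the 100 brightest probes.

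MiRNAs typical of other cell types did not move as 1 group. No muscle probe (8 on the panel) and no fibroblast and smooth muscle probe (6 on the panel) was tested. Of the blood cell list both tested probes were called lower on the deposited scale: miR-155-5p, whose siYAP readings of 1 count leave the size open, and the erythroid miR-144-3p, which was 269 ± 65 in siCtrl and 163 ± 32 in siYAP. Of the neural list miR-9-5p rose from 187 ± 53 to 833 ± 69 (limma adjusted p = 3.2e-07) and miR-129-2-3p from 72.3 ± 22.8 to 151.1 ± 14.1 (7.4e-04), while miR-128 was 63.3 ± 1.8 and 86.4 ± 15.6 (0.135); the list median of 1.08, which is that of miR-129-2-3p, turned negative under 3 of the other scalings, and miR-128 was called lower with scaling on the 100 brightest probes. MiR-126-3p, encoded in an intron of the endothelial gene EGFL7, rose from 170 ± 58 to 743 ± 44 (adjusted p = 3.0e-07), in the same direction under each scaling. Neither pluripotency probe passed the test on the deposited scale, with miR-302d-3p at 171 ± 10 and 145 ± 74 and miR-371a-3p at 74.7 ± 6.3 and 85.0 ± 15.1. Both were called lower under 4 of the 6 other scalings, and miR-302d-3p also with quantile normalization. Of the imprinted 14q32 cluster 4 of 51 probes were tested, and their median was -0.52 (camera adjusted p = 0.136, adjusted p = 0.022 without siCtrl 2, and adjusted p = 0.851 with an estimated correlation). There miR-494 rose from 60.2 ± 4.6 to 105.9 ± 29.5 (adjusted p = 0.01), a difference that turned negative with 4 scalings and did not pass the test without siCtrl 2 (0.0766) or without siYAP 1 (0.211). MiR-411-5p was 72.5 ± 0.5 and 51.6 ± 8.8, miR-337-3p 54.0 ± 3.1 and 36.5 ± 2.5, and miR-770-5p 54.1 ± 11.8 and 35.7 ± 0.3 (adjusted p = 0.0867, 0.054 and 0.0518). These 3 were called lower under each of the 6 other scalings, which lower siYAP. The fixed list for the placental 19q13 cluster was written without miR-1283, and 2 of the 41 probes on that list were tested. The probe shared by miR-520d-5p, miR-518a-5p and miR-527 fell, and miR-520h was 71.0 ± 2.6 and 54.6 ± 29.3 (adjusted p = 0.125). Both were called lower under 5 of the 6 other scalings, and the shared probe also with quantile normalization.

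**Figure D3:**
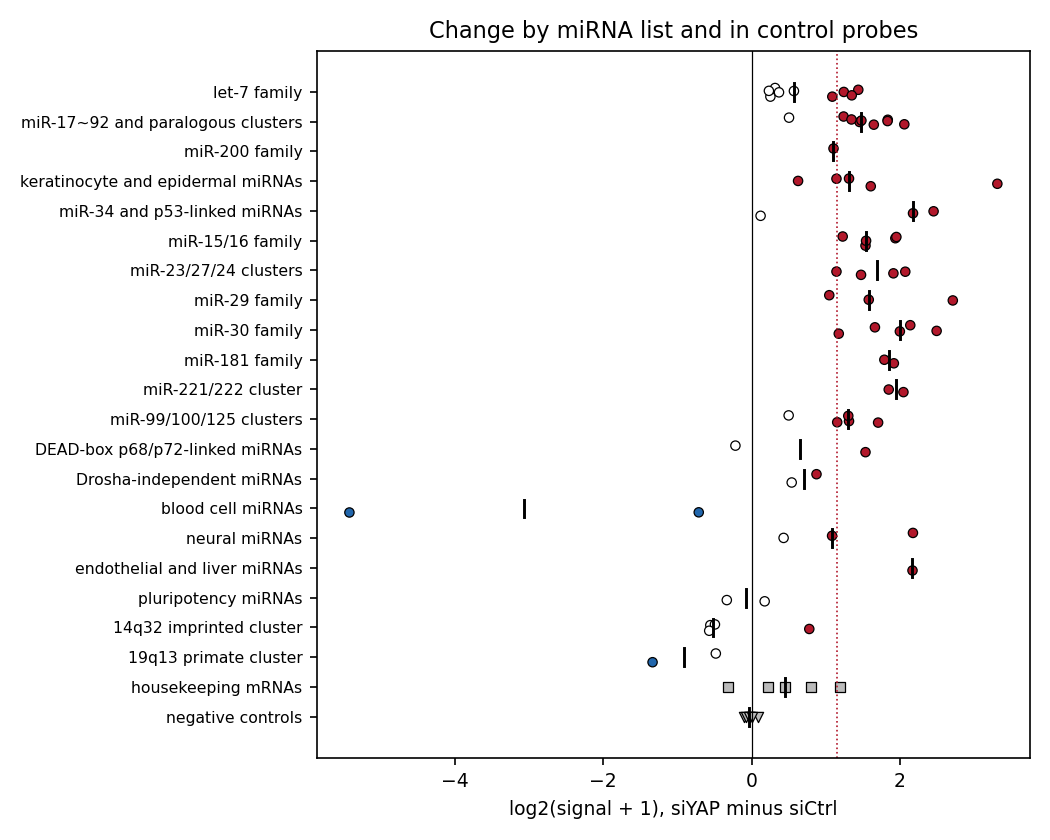
Log2 difference in signal (siYAP minus siCtrl, deposited scale) of each tested member of the 20 fixed lists with a tested probe, and of the housekeeping and negative controls; red points rose, blue points fell, open points did not pass the test, black bars are medians and the dotted line is the median of all tested probes, 1.15. The medians of 9 lists stayed above 0 under each of 6 other scalings, those of 7 lists, let-7 among them, changed sign under at least 1. Those of 4 lay below 0 on the deposited scale, which scalings that lower siYAP do not test.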

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

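The tests of lane scaling, RNA amount, a common gain, unequal noise of the controls, a floor of 1 count and a fall to non-target level were chosen after the results they bear on were seen, and the tests of a brightness gain and a shared axis were chosen before.

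The probe for the rice miRNA osa-miR442 stood above the control samples in data outside the comparison: its mean was 115.4 in siYAP against 39.1 in siCtrl, with counts of 34 and 42 in siCtrl and 106 and 126 in siYAP. The other 4 plant or worm probes differed by between -0.42 and 0.17 on the log2 scale.

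The first pattern is the rise of miRNA signal across the panel, with a median log2 difference of 1.15. The values argue against lane scaling, since the negative controls put on the same scale differed by a mean of -0.025 (SE 0.027). For 1 gain common to every miRNA, the variance of the differences over 114 probes above background in all samples was 7.42 times that expected from the replicates. Background was not subtracted there, so under 1 gain dim probes would differ less than bright ones, and this ratio alone does not exclude it. Of the 114 probes 77 were called higher and 5 lower, and 1 common gain would not lower some beside the rises. That argues against such a gain as the whole change. More RNA in the siYAP lanes cannot be told apart from a rise per cell. The housekeeping mRNAs rose by a mean of 0.468, with 95% bounds of -0.243 to 1.178 taken over the 5 mRNAs and not over samples. These bounds just include the miRNA median of 1.15, but changes of dim miRNA probes are understated. The miRNA median was 1.46 for probes with a mean above 100 and 1.42 with background subtracted, both above the bounds. That mean was taken over all 4 samples, siYAP included, and neither median was given an error. These medians therefore do not decide on the RNA amount. The 5 mRNAs ranged from -0.32 (ACTB) to 1.19 (GAPDH), so they do not settle the RNA amount. A rise of many mature miRNAs on loss of YAP stays open as a hypothesis beside a larger RNA input. The 25 rises that remained called under 6 other scalings do not decide between them, since scaling on the miRNAs keeps probes that rose more than the panel.

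The second pattern is that siCtrl 2 lay nearer to the siYAP samples than siCtrl 1, with 140 of 182 tested probes higher in siCtrl 2. Across probes, which are not independent replicates, the difference between the control samples correlated with the siYAP effect (Pearson r = 0.486, Spearman rho = 0.522), while the difference between the siYAP samples did not follow it (r = -0.036). With mean signal taken out, to allow for a gain that grows with probe brightness, the correlation was 0.38. That value still contains the noise of the shared siCtrl readings. Both differences contain the siCtrl readings, so noise in siCtrl 1 alone would give a positive correlation, with a slope of the effect on the control difference of at most 0.5. The slope was 1.228 (SE 0.165), and 1.10 (SE 0.16) over the 114 probes above background in all samples, which argues against such noise as the whole of it. Brightness was not taken out of these slopes, so a brightness gain and noise acting together were not tested and are not excluded. A candidate explanation is a state that varied between the control samples along the same axis as the YAP effect. With 2 control samples its nature was not tested. A difference in RNA input between the control samples was not tested either and is not excluded. The summed human miRNA signal was 57347 in siCtrl 1 and 77729 in siCtrl 2. Of the housekeeping mRNAs, B2M was higher in siCtrl 2 (516.4 and 558.3), while ACTB, GAPDH, RPL19 and RPLP0 were lower there.

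The third pattern is miR-155-5p at 1 count in both siYAP samples. Both readings lay below every negative control, of which 8 was the lowest count. A floor of 1 count set during processing may account for the exact value: 20 human miRNA readings were at 1 count, 5 at 2 counts and 0 at 0. MiR-143-3p, miR-363-3p and miR-549 read 1 count in all 4 samples. In the order siCtrl 1, siCtrl 2, siYAP 1 and siYAP 2, miR-4443 read 1, 1, 1 and 55 and miR-1253 read 52, 2, 1 and 1. Whether the miR-155-5p signal fell or its readings were lost before deposit cannot be told apart. Of the 551 probes above background in no sample, 3 read as low in both siYAP samples and 17 read below every negative control there. The 3 were the probes at 1 count in all 4 samples, so no other such probe reached that reading. They do not show that a fall to the level of probes without a target ends at 1 count. The size of any fall is not settled.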

How the results depend on the processing

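The edgeR and DESeq2 fits, background subtraction, leaving out probes with a reading of 1 count and rescaling on the positive controls were chosen after seeing the data. Directions of the panel depend on the scale. The 6 other scalings lower siYAP relative to siCtrl, so they do not test the 11 falls. Scaling on the miRNAs themselves (centring, the 100 brightest probes, the total, quantiles or TMM) removes by construction a shift that most miRNAs share, so it cannot tell a shared rise from a difference between lanes. Rescaling on the 5 housekeeping mRNAs, which differed from each other, moved the median of the tested probes from 1.15 to 0.68. Count models on the authors' scale called 139 probes (edgeR, 124 higher and 15 lower, all 131 limma calls among them) and 126 (DESeq2, 119 higher and 7 lower), against 131 with limma. Because the values were deposited scaled, the planned choices for raw counts (DESeq2 or limma in place of edgeR, and DESeq2 or positive control factors in place of TMM) did not apply as written. What signal over background limits is the dim end: 618 of the 800 probes were not tested. Of the 120 rises, 74 were above background in both siCtrl samples and 21 were below it in both.

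In order of called, higher and lower probes, then the median log2 difference and the percentage of probes above 0, the deposited scale gave 131, 120, 11, 1.15 and 83%. Centring on the median tested probe gave 88, 42, 46, 0.18 and 57.7%. The 100 brightest probes gave 88, 26, 62, -0.19 and 38.5%. The miRNA total gave 86, 35, 51, 0.009 and 50.5%. The housekeeping mRNAs gave 87, 66, 21, 0.68 and 72%. Quantile normalization gave 69, 37, 32, 0.10 and 55.5%. TMM gave 87, 37, 50, 0.07 and 52.2%. Probes called under these 6 settings in the direction opposite to the deposited scale numbered 3, all with scaling on the 100 brightest probes: miR-455-3p, and miR-421 (-0.56) and miR-423-3p (-0.56), the last pair named after their values were seen.

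Other filters changed counts mainly through the number of probes tested. With no filter 170 of 800 probes were called, 45 of them lower, the median was -0.20 and 38.2% were above 0, since dim probes lay slightly lower in siYAP. With probes above background in all samples 82 of 114 were called, 77 higher and 5 lower, and 86% were above 0. With a mean above 100, 83 of 97 were called, 79 higher and 4 lower, with a median of 1.46 and 91.8% above 0. A background of 3 SD left 7 lower calls, a median of 1.23 and 88.1% above 0. The median was 1.05 with a pseudocount of 10, 0.74 with 50 and 1.42 with background subtracted. Without 1 sample, with the lone sample of its group assumed to vary like the other group, 94 to 129 probes were called, 88 to 119 higher and 6 to 10 lower (6 without siYAP 1, of which 4 were among the 11 falls, and 6 without siYAP 2, all among them), the median was 0.921 to 1.369, 81.9% to 84.1% were above 0, and 0 to 1 lists were called. The fits without 1 sample have fewer samples, and the cause of their fewer calls beyond that was not tested. The same-numbered samples did not deviate together (r = 0.06), so the numbers were not taken to pair the samples; with the replicate block limma called 129 probes, 128 of them shared.

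Camera called 0 of 11 lists on the deposited scale and 11 of 20 with no filter, 9 of them among the 11 lists tested with the filter and the other 2 (the miR-181 family and the 19q13 cluster) with too few probes under it. With no filter the dim probes join the comparison and let-7 turned from below the other probes to 0.77 above them. Camera called 1, the 14q32 cluster, with background subtracted and without siCtrl 2, and the cause was not tested. Fry called 8, and the other settings called 0.

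Among single named miRNAs, 68 combinations of miRNA and setting changed sign, 17 of them uncalled in both settings and the other 51, listed next, each under a scaling on the miRNAs themselves. Another 167 kept the sign but lost the call, 45 kept the sign and gained one, and 1211 kept both sign and side of the threshold. With the 100 brightest probes the log2 differences were -0.11 for miR-106a-5p/17-5p, -0.11 for let-7a-5p, -0.001 for let-7g-5p, -0.78 for let-7f-5p, -0.23 for miR-200c-3p, -0.037 for miR-125b-5p, -0.20 for miR-24-3p, -0.71 for miR-455-3p, -1.22 for miR-192-5p, -0.12 for miR-503, -0.29 for miR-29a-3p, -0.16 for miR-30c-5p, -0.046 for miR-99b-5p, -0.19 for miR-99a-5p, -0.80 for miR-484, -0.45 for miR-320e, -0.25 for miR-129-2-3p, -0.90 for miR-128, -1.16 for miR-371a-3p and -0.56 for miR-494. With quantile normalization they were -0.26 for miR-106a-5p/17-5p, -0.066 for let-7e-5p, -0.62 for let-7f-5p, -0.17 for miR-125b-5p, -0.27 for miR-455-3p, -0.94 for miR-192-5p, -0.03 for miR-503, -0.25 for miR-99b-5p and -0.075 for miR-99a-5p. With the miRNA total they were -0.57 for let-7f-5p, -0.028 for miR-200c-3p, -0.51 for miR-455-3p, -1.02 for miR-192-5p, -0.089 for miR-29a-3p, -0.25 for miR-320e, -0.052 for miR-129-2-3p, -0.96 for miR-371a-3p and -0.36 for miR-494. With TMM they were -0.52 for let-7f-5p, -0.45 for miR-455-3p, -0.99 for miR-192-5p, -0.044 for miR-29a-3p, -0.22 for miR-320e, -0.013 for miR-129-2-3p, -0.94 for miR-371a-3p and -0.32 for miR-494. With centring they were -0.34 for miR-455-3p, -0.85 for miR-192-5p, -0.093 for miR-320e, -0.79 for miR-371a-3p and -0.19 for miR-494. Of these, let-7f-5p, miR-192-5p, miR-484, miR-128 and miR-371a-3p had not passed the test on the deposited scale.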

Other observations

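The test of neighbouring genes was chosen before its result was seen, and the miRNAs named next were picked after their values were seen. Among miRNAs outside the fixed lists, the sensory and epithelial miR-183/96/182 cluster rose on the deposited scale: miR-182-5p from 57.5 ± 16.5 to 193.8 ± 8.6, miR-183-5p from 118 ± 24 to 345 ± 27 and miR-96-5p from 75.5 ± 14 to 216.8 ± 18.1 (SD, n = 2; limma adjusted p = 6.1e-07, 1.7e-05 and 9.6e-06). In siCtrl 1 miR-182-5p was below background (45.81), so the size of its rise is uncertain. MiR-148a-3p and miR-148b-3p, which share a seed, were 578 ± 268 and 367 ± 49 in siCtrl and 2604 ± 288 and 1424 ± 71 in siYAP (adjusted p = 7.3e-06 and 9.5e-06). MiR-132-3p, a CREB target, rose from 94.1 ± 6.4 to 462.4 ± 137.6 (adjusted p = 3.0e-08) and miR-582-5p from 56.6 ± 0.5 to 246.1 ± 1.3 (1.9e-08). Of the 6 other scalings, miR-182-5p was called higher under 5, miR-183-5p and miR-96-5p under 1 each, and the last 4 named under all 6.

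Probes of similar names or from 1 cluster did not always move together, and the differences between them were not tested. MiR-378e fell from 1189 to 473, while miR-378g rose from 51.4 to 139.4 and the probe shared by miR-378a-3p and miR-378i from 162 to 401. In siCtrl 1 miR-378g was below background (46.85). In the miR-17~92 cluster miR-92a-3p had a log2 difference of 0.51 (limma adjusted p = 0.28) beside 1.84 for miR-19a-3p and 1.65 for miR-19b-3p. MiR-192-5p had 0.12 beside 2.17 for its neighbour miR-194-5p, and miR-188-5p had -0.10 (limma adjusted p = 0.733) beside 1.53 for miR-660-5p and 0.97 for miR-532-5p. MiR-362-5p, another neighbour of miR-188-5p, was below background in siCtrl and rose at least 3.44-fold.

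One hypothesis was that miRNA genes lying within 10000 bp of each other change by similar amounts, as they would if shared transcripts set the change. Over 46 pairs with different family numbers in their names the mean absolute difference in log2 change was 0.725. It was 1.016 for probes shuffled among all mapped probes of like brightness (permutation p = 0.0180, 10000 shuffles). Families were told apart by name only, so the pairs still held related miRNAs, such as miR-15a-5p and miR-16-5p. When probes were shuffled only among those that have a neighbour, the shuffled mean was 0.754 (permutation p = 0.3609). Clustered miRNAs were thus more alike in change than the panel, but not shown to be more alike within a cluster than between clusters, and the hypothesis stays undecided.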
